A study of Bos taurus with 6 samples.

How the data were processed

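Gene expression was compared between bovine cumulus cells, the somatic cells that surround the oocyte in the follicle, from complexes cultured with or without FID. FID is a mixture of 100 µM forskolin, an activator of adenylyl cyclase, with 500 µM IBMX and 50 µM dipyridamole, which inhibit phosphodiesterases. The complexes came from ovaries of Holstein cows collected at slaughter, per the labels' protocols. The names of the control samples carry 6 h, while the culture protocol gives 22 to 24 h of maturation for both conditions, so the time in culture behind the comparison is not settled here. RNA was amplified in a T7-based procedure and labelled with Cy3 or Cy5 by a non-enzymatic chemistry, per the labels' protocols, and FID and control RNA were hybridised together on Agilent 2-colour arrays. The 6 arrays held 3 biological replicates, numbered 1, 2 and 4, each on 2 arrays with the dyes exchanged.

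The deposited scanner files gave raw spot intensity and local background intensity per channel, at 532 nm for Cy3 and 635 nm for Cy5, with no background subtracted, per the file headers. The scanner software was not given in the sources used here. The authors also deposited log2 ratios in a pair of tables that were identical to each other (largest difference 0), and their normalization method was not given in the sources used here. Against the scanner intensities these ratios ran as Cy5 over Cy3 on all 6 arrays, with slopes of 0.949 to 1.02 over 4272 bright probes. Their medians lay between -0.0185 and -0.00285, and they correlated with the ratios computed here at 0.994 to 0.998. Scale and direction were settled by this comparison, while how the ratios were centred stays unknown beyond those medians. They were used only as an alternative.

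Each array had 45220 spots, among them 1418 control spots and 8 spots without an identifier, which were left out of all tests. The remaining 43794 probes were named through the platform annotation, in which 21790 had 1 gene symbol, 22004 had none and 0 had several. Of 15229 distinct symbols, 14114 matched a current RefSeq symbol, and the symbol of the annotation was kept for the others. A genome build for these probes was not given in the sources used here, so no coordinates are printed. Intensities were background corrected with limma 3.58.1 in R 4.3.3 by the normexp method with an offset of 50, and normalized by loess within each array with control spots at weight 0. No normalization was applied between arrays. The sign of the 3 arrays with FID in Cy3 was turned, so that all ratios ran as FID over control. The arrays of a replicate were then averaged, which cancels a dye effect and leaves 3 ratios per probe.

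Between 13 and 88 spots per array were marked in the scanner files as to be ignored. In the first run these spots were kept in the background fit and left out only afterwards, and 0 probes then passed the test. The log2 ratios of the array of replicate 2 with FID in Cy3 had an SD of 0.46 in that run, and 0.71 with the marked spots left out. Among its 61 marked spots, 1 had a local background of 65500 in Cy3, against at most 616 at unmarked spots. With only this spot left out of the background fit the SD was 0.71 and 554 probes passed, while with only this one of its marked spots kept the SD was 0.46 and 0 probes passed. This test of the spot was added after the results were seen. The marked spots were therefore left out before the background fit. This change was made after the count of 0 had been seen, and the first run is kept as an alternative.

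A probe was tested where its signal exceeded the 95th percentile of the 153 negative control spots of its channel, in FID or in control, on at least 4 of the 6 arrays. This left 32124 probes, of which 16894 carried a symbol, for 12363 genes. A gene was represented by its tested probe with the highest mean intensity. Ratios were tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment over all tested probes at a threshold of 0.05. The fit had 2 residual and 1.85 prior degrees of freedom. The precision depended on both the number of replicates, 3, and the spread between them. Signal over background set which probes could be measured: 51.2% to 84.3% of probes per array exceeded the negative controls in FID and 58.5% to 86.7% in control. By dye these shares were 75.1% to 86.7% in Cy3 and 51.2% to 71.3% in Cy5. The local background of 16 to 59 units lay below the medians of the negative control spots, which were 135 to 219 in Cy3 and 103 to 163 in Cy5. Ratios of dim probes are therefore compressed towards 0.

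For a probe above background on no array of a condition, or saturated on every array, only a bound is given. Where only some arrays of a condition were above background, their number is given beside the estimate. It sets the mean of the brighter condition against the dimmer one, with a probe below background placed on each array at the lowest signal among probes above background, or at its own signal where that was higher, on channel values after loess and Aquantile normalization. The dye swaps were balanced in these means.

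In total 31 gene lists were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Some genes belong to several lists, so the lists are not independent of each other. Tests of the comparison, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the treatment of marked spots. Tests of explanations were chosen after the results were seen, except the counts over choices of sign. The genes named were the 10 largest rises and the 10 largest falls past the threshold that had the same direction in 3 replicates and on 6 arrays, uncharacterised loci passed over. To these came up to 4 members past the threshold of each list, or the 2 with the smallest p where fewer than 2 passed, and 23 genes fixed by name. Other genes appear only where they are said to have been chosen after their values were seen.

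The procedure was tested on simulated data for 32124 probes with the real spread between replicates. With 200 probes changed, 9.38% of those changed by 1 on the log2 scale, 57.0% of those changed by 2 and 78.9% of those changed by 3 were recovered, and 7 of 103 calls were false. With 2613, 2775 and 2643 probes changed by these sizes, 69.8%, 97.0% and 99.8% were recovered, and 309 of 7463 calls were false. Changes of 1, 2 and 3 were estimated in the first simulation at medians of 0.66, 1.26 and 1.81, and among the brightest probes at 0.99, 1.93 and 2.80. A list shifted by -1 was found in 20 of 20 simulated runs on 12363 genes drawn independently, with 0 false list calls. In the real data the estimated correlation between members was 0.13 to 0.86 for the 5 lists called below. These runs therefore do not show how often lists of correlated genes are called falsely.

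Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, the use of the dye swap arrays, the pairing, the variance model, the authors' deposited ratios, the fold threshold, the rule from probes to genes, the set test and the omission of each replicate. Slide as a block was not run, since the files used give no slide. Figures were drawn with matplotlib 3.10.9.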

Results

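Transcript levels were measured on 6 two-colour arrays in cumulus cells cultured with FID against control cells, as 3 biological replicates with a dye swap each. The comparison addresses which transcripts differ in cumulus cells cultured with FID, a mixture that acts on adenylyl cyclase and phosphodiesterases. Cyclic AMP itself was not measured here. Whether both conditions had the same time in culture is not settled either, so a difference in time could not be excluded. Of 43794 probes on the array, 32124 exceeded background and were tested. Median intensities per array were 173 to 294 in FID and 143 to 255 in control. Between 2 and 79 spots per array were saturated in FID, and between 1 and 43 in control. Saturation went with the dye, at 30 to 79 spots in Cy5 and 1 to 4 in Cy3, whichever condition the dye held.

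Among named genes, 292 of 12363 differed between FID and control, 132 higher and 160 lower. JUND, a component of the AP-1 transcription factor, rose by 3.36 ± 0.16 on the log2 scale (SE, n = 3 replicates), or 10.3-fold, on probe EMBV3_21587. GRASP, a scaffold protein of receptor trafficking, rose by 3.27 ± 0.18 and MAP3K2, a kinase of the MAP kinase cascades, by 3.24 ± 0.23. RSAD2, which encodes the antiviral protein viperin, fell by 5.60 ± 0.45 on the log2 scale, or 48.7-fold, on probe EMBV3_06531. OLR1, a receptor for oxidised low-density lipoprotein, fell by 5.36 ± 0.34, and exceeded background in FID on 3 of 6 arrays. IFIH1, a sensor of viral RNA, fell by 4.88 ± 0.44. RSAD2 and IFIH1 each exceeded background in FID on 5 of 6 arrays.

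Other rises among the 10 largest were SLC2A3, a glucose transporter, by 2.92 ± 0.09 with saturation in FID on 2 arrays, and TLE1, a transcriptional corepressor, by 2.78 ± 0.24. BTG2, an antiproliferative gene, rose by 2.71 ± 0.12, and ITPKA, which phosphorylates inositol trisphosphate, by 2.68 ± 0.25. SMPD3, a neutral sphingomyelinase, rose by 2.67 ± 0.10 and NR4A2, an orphan nuclear receptor, by 2.63 ± 0.22. ARFGAP3, a regulator of Golgi transport, rose by 2.61 ± 0.19 on its brightest probe, while 1 of its 4 tested probes had the opposite sign. Further falls were NPY1R, a neuropeptide Y receptor, with -3.88 ± 0.23 on the only one of its 3 tested probes to pass, and NDP, a secreted ligand of frizzled receptors, with -3.78 ± 0.13. The fall was -3.54 ± 0.33 for ANXA1, an annexin, -3.50 ± 0.36 for OAS1, an oligoadenylate synthetase, and -3.49 ± 0.17 for AXL, a receptor tyrosine kinase. NMI, an interferon-induced protein, fell by 3.41 ± 0.17 and ZBTB38, a zinc finger protein, by 3.09 ± 0.19.

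**Figure D1:**
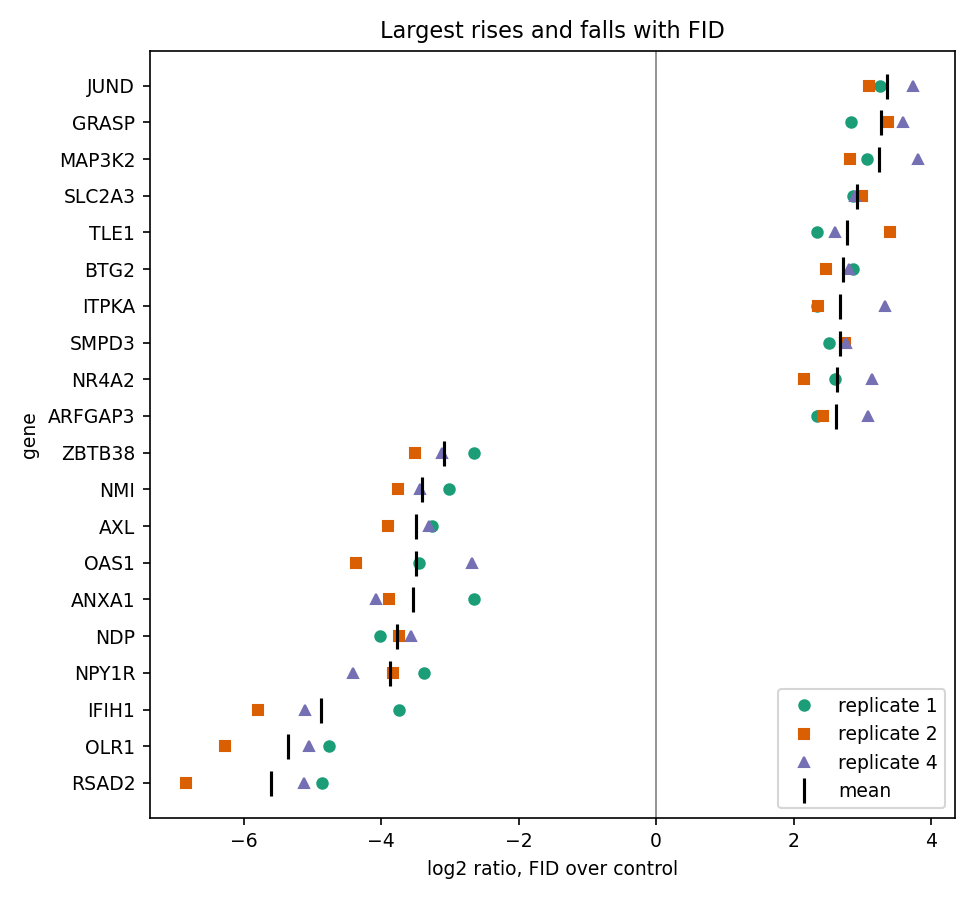
Log2 ratio of FID over control on the horizontal axis for the 10 named genes with the largest rises and the 10 with the largest falls. Points are the 3 replicates, each the mean of its 2 dye swap arrays, and the vertical bar is their mean, from -5.60 for RSAD2 to 3.36 for JUND.

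Over all probes, 557 passed limma's test after Benjamini-Hochberg adjustment, 248 higher and 309 lower in FID, and 202 of them had no gene symbol. Their adjusted p lay between 0.0476 and the threshold, while 7561 probes (23.5%) had an unadjusted p under 0.05. The median fold among the 292 genes was 2.73, and 289 of them had the same direction on 6 of 6 arrays. Among 99 changed genes with more than 1 tested probe, 24 had a probe of opposite sign. With median centring in place of loess the division was 234 higher and 529 lower probes, and 122 higher and 281 lower genes. With the 6 arrays in 1 fit, a dye term and the replicate as a random block (the block fit below), 5177 probes and 2567 genes passed, all 557 probes among them. This fit counts both dye swap arrays towards its degrees of freedom, with 1 correlation of 0.608 within replicates for all probes. The biological replicates remain 3, so values from the block fit are an alternative and no independent support. Of 55 named genes that did not pass, 42 passed in the block fit, all except BTC, CD74, CYP19A1, FSHR, INHBA, KDR, MOS, PDE3A, PDE3B, PDE4B, PTCH1, PTGS2 and TEK. The count fell to 0 probes in limma under 8 other settings, which gave 4863 to 7428 probes at an unadjusted p under 0.05 and smallest adjusted p of 0.0505 to 0.249. These include the first run of the procedure, in which spots marked as to be ignored were still in the background fit, and the authors' deposited ratios.

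Of 31 gene lists, 5 were shifted in camera with its preset correlation, and none was called in camera with an estimated correlation. There the adjusted p was 0.853 for each of the 5 and for every other list. Of the 31, 0 had an unadjusted p under 0.05 in that setting. The value of 0.853 therefore does not set the 5 lists apart from the others and says little about any single list. The early genes that respond to cyclic AMP were higher in FID. Of 28 measured members, 6 rose, 0 fell and 22 did not pass over all genes. When adjusted over the list alone, 20 were higher and 1 was lower. The list median was 1.12 on the log2 scale, with 1.18, 0.79 and 1.35 in replicates 1, 2 and 4 (camera adjusted p = 1.32e-08, with 20 higher and 1 lower in the block fit). JUND, BTG2 and NR4A2 were among the 6. NR4A1, another orphan nuclear receptor, was saturated in FID on 6 of 6 arrays and was at least 5.99-fold higher. CREM, a cyclic AMP-responsive transcription factor above background in control on 3 of 6 arrays, had 0.74 ± 0.15 (adjusted p = 0.0939), and its other tested probe had the opposite sign.

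Interferon-stimulated genes were lower in FID. Of 24 measured members, 7 fell over all genes, 0 rose and 17 did not pass, while 18 were lower when adjusted over the list alone. The fitted ratio was negative for all 24. The list median was -1.43, with -1.05, -2.07 and -1.55 in the replicates (camera adjusted p = 1.08e-10, with 0 higher and 17 lower in the block fit, and 0.853 as the adjusted p with an estimated correlation). RSAD2, IFIH1 and OAS1 had the largest falls among members that passed, followed by IFIT5, an interferon-induced RNA-binding protein, with -2.52 ± 0.20. Markers of blood and immune cells, measured for 15 genes, had a median of 0.09 (camera adjusted p = 0.221, with 2 higher and 0 lower in the block fit, and 0.0377 with median centring), with 0 members past the threshold over all genes and 0 when adjusted over the list alone. CD74, a chaperone of antigen presentation, had 0.28 ± 0.08 (adjusted p = 0.159). LYZ, lysozyme, was not above background in control, was above it in FID on 4 of 6 arrays, and was at least 1.52-fold brighter in FID, with an adjusted p of 0.0723.

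Oocyte markers were higher in FID as a list, with no single member past the threshold. The ratio was positive for 23 of 23 members, and 0 rose over all genes or when adjusted over the list alone. The median was 0.98, with 0.72, 2.44 and 0.10 in replicates 1, 2 and 4 (camera adjusted p = 0.00047, with 2 higher and 0 lower in the block fit, and 0.853 as the adjusted p with an estimated correlation of 0.862). Without replicate 2 the list median was 0.41. The call was lost among probes above background in both conditions on all 6 arrays (median 0.66 over 8 members, each on its brightest such probe, camera adjusted p = 0.115). GDF9, a growth factor secreted by the oocyte, had 1.39 ± 0.47 (adjusted p = 0.200), above background on 5 of 6 arrays in FID and 4 of 6 in control. DPPA3, a maternal-effect gene above background in control on 4 of 6 arrays, had 2.29 ± 0.54. MOS, a kinase of oocyte meiosis, had 0.50 ± 0.13 (adjusted p = 0.132). It was higher in FID on only 3 of 6 arrays. Its dye effect of -0.80 in the block fit was larger in size than its ratio.

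**Figure D2:**
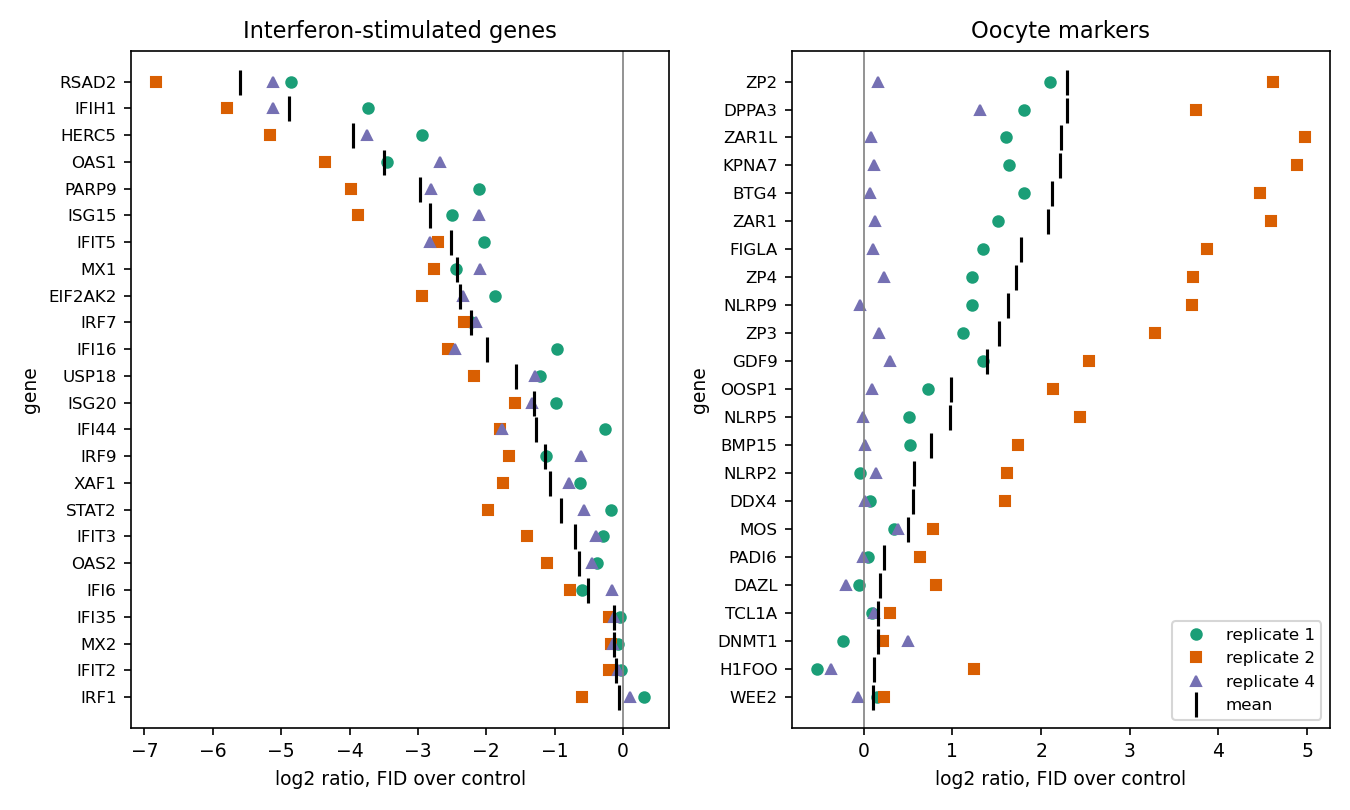
Log2 ratio of FID over control on the horizontal axes for each measured member of the interferon-stimulated genes (left) and the oocyte markers (right). Points are the 3 replicates, each the mean of its dye swap arrays, and bars their mean. The interferon list had replicate medians of -1.05, -2.07 and -1.55, and the oocyte markers 0.72, 2.44 and 0.10.

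Actin, adhesion and YAP-SRF target genes were lower in FID, with a median of -0.54 over 25 members (camera adjusted p = 0.00324, with 2 higher and 10 lower in the block fit, and 0.853 as the adjusted p with an estimated correlation). The replicate medians were -0.63, -0.59 and -0.16. Over all genes 1 member fell and 24 did not pass, and 4 were lower and 1 higher when adjusted over the list alone. The member that fell was ANKRD1, a YAP-responsive nuclear protein, with -1.40 ± 0.10 and with FID above background on 5 of 6 arrays. TPM4, a tropomyosin, had -1.21 ± 0.13 (adjusted p = 0.0515) on a probe saturated in control on 2 arrays, and the lowest of its 3 tested probes had -1.95. Markers of stroma and fibroblasts were not shifted (median -0.39, 13 members, camera adjusted p = 0.185, with 0 higher and 4 lower in the block fit), but were called as lower without replicate 4 (median -0.46, camera adjusted p = 0.00392). Of these, PDGFRA, a growth factor receptor, fell by 2.09 ± 0.14 and LUM, a collagen-binding proteoglycan, by 1.49 ± 0.14, and 3 members were lower when adjusted over the list alone.

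Cell cycle inhibitors and p53 targets were higher in FID, with a median of 0.48 over 19 members (camera adjusted p = 0.0115, with 9 higher and 1 lower in the block fit, and 0.853 as the adjusted p with an estimated correlation). BTG2, which is also in the list of early genes, and GADD45A, a stress-induced gene of growth arrest, rose, the latter by 1.68 ± 0.15. The other 17 did not pass, and 10 were higher and 2 lower when adjusted over the list alone. With only the arrays that had FID in Cy5, the list was not called (median 0.38, camera adjusted p = 0.0687). In the list of cell cycle and DNA replication, 2 of 39 members rose and 4 were higher when adjusted over the list alone (median 0.16, camera adjusted p = 0.221, with 8 higher and 1 lower in the block fit). Without replicate 4 this list was called as higher (median 0.20, camera adjusted p = 0.00766). The 2 that rose were MCM5, a subunit of the replicative helicase, with 1.39 ± 0.09, and RRM2, a subunit of ribonucleotide reductase, with 1.20 ± 0.11. In the apoptosis list, 1 of 19 members passed (median 0.05, camera adjusted p = 0.664, with 5 higher and 3 lower in the block fit), and 5 were higher and 4 lower when adjusted over the list alone. This was CASP8, the initiator caspase of death receptors, with -2.93 ± 0.25 and with FID above background on 4 of 6 arrays. BNIP3, a mitochondrial protein of hypoxia and cell death, had 1.52 ± 0.18 (adjusted p = 0.0537).

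**Figure D3:**
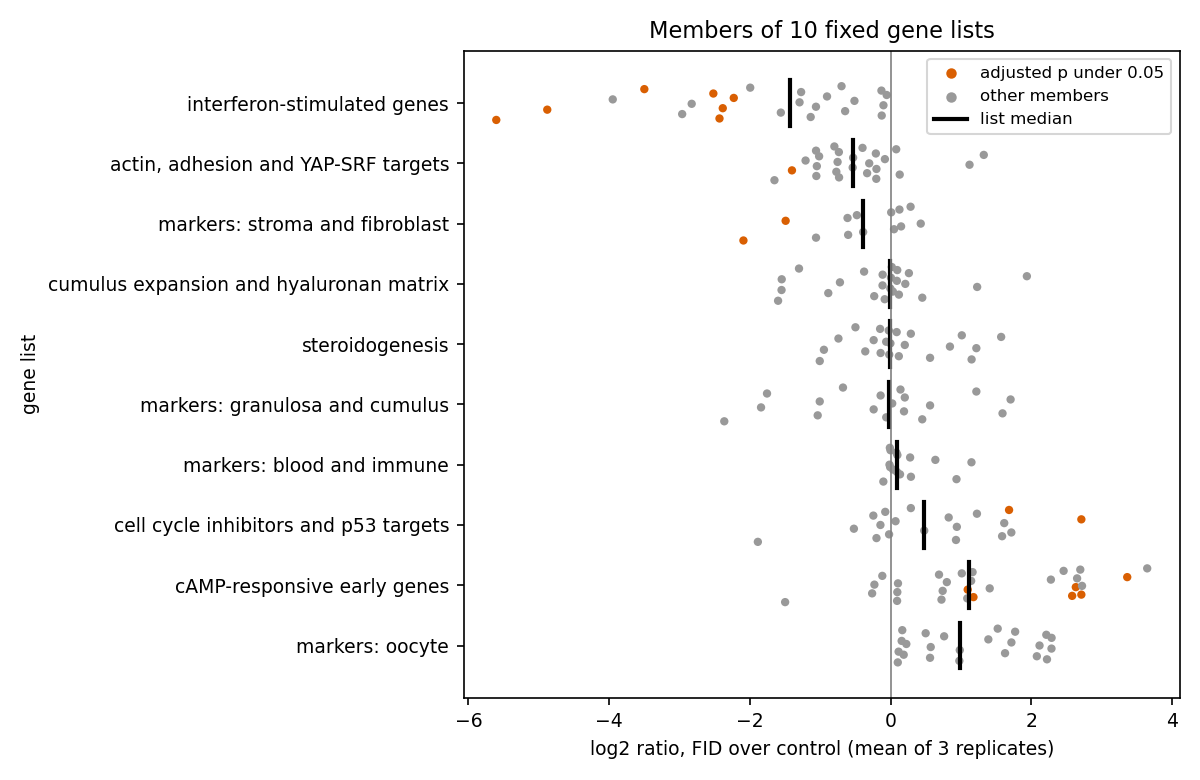
Log2 ratio of FID over control on the horizontal axis, as the mean of 3 replicates, for the measured members of 10 gene lists. Coloured points passed the test over all probes and grey points did not, and bars are list medians, from -1.43 for interferon-stimulated genes to 1.12 for early genes.

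Genes of cumulus expansion and the hyaluronan matrix showed no shift as a list (median -0.00 over 23 members, camera adjusted p = 0.805, with 3 higher and 5 lower in the block fit). None passed over all genes, and 3 were higher and 2 lower when adjusted over the list alone. HAS2, the hyaluronan synthase of cumulus expansion, had -1.60 ± 0.29 (adjusted p = 0.0826). UGDH, which makes a hyaluronan precursor, had -1.55 ± 0.27 (adjusted p = 0.0771) and PTX3, a matrix-organising pentraxin, had -1.55 ± 0.41 (adjusted p = 0.134). TNFAIP6, which modifies hyaluronan, had -0.72 ± 0.17 (adjusted p = 0.115) and SDC4, a syndecan, had 0.45 ± 0.08 (adjusted p = 0.0811). PTGS2, an inducible cyclooxygenase, had 0.21 ± 0.10, above background on 4 of 6 arrays in FID and 5 of 6 in control. In the block fit the adjusted p was 0.00565 for HAS2, 0.00412 for UGDH, 0.0133 for PTX3, 0.0340 for TNFAIP6 and 0.0288 for SDC4. ADAMTS1 and HAPLN3, chosen after their values were seen, went the other way from HAS2, with 1.94 ± 0.41 and 1.23 ± 0.24. Neither passed over all genes (adjusted p = 0.0976 and 0.0867). Their adjusted p in the block fit was 0.00563 and 0.00573. In the prostaglandin list, 1 of 17 members passed, both over all genes and when adjusted over the list alone (median 0.00, camera adjusted p = 0.831, with 1 higher and 1 lower in the block fit). This was PTGDS, a prostaglandin D synthase, which rose by 1.85 ± 0.10, and PLA2G4A, a phospholipase, had -0.88 ± 0.17.

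In the steroidogenesis list, 0 of 22 members passed over all genes or when adjusted over the list alone (median -0.01, camera adjusted p = 0.831, with 4 higher and 1 lower in the block fit). STAR, which carries cholesterol into mitochondria, had 1.57 ± 0.57 (adjusted p = 0.221), with 1.01, 3.12 and 0.58 in replicates 1, 2 and 4. CYP11A1, the side-chain cleavage enzyme, had 1.01 ± 0.24 (adjusted p = 0.114), NR5A2, a nuclear receptor of steroidogenic cells, 1.22 ± 0.30 and CYP19A1, aromatase, 0.20 ± 0.18. Cholesterol biosynthesis and uptake had a median of -0.43 over 22 members (camera adjusted p = 0.185, with 1 higher and 3 lower in the block fit), with 0 passing over all genes and 0 when adjusted over the list alone. It was called as lower with median centring (median -0.56, camera adjusted p = 0.0456) and without replicate 1 (median -0.48, camera adjusted p = 0.00881). Its enzymes NSDHL and TM7SF2 had -0.88 ± 0.16 and 0.62 ± 0.11, and the other tested probe of TM7SF2 had the opposite sign.

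Of 29 genes of gonadotrophin, steroid and TGF-beta family hormone signals, 0 passed over all genes, and 3 were higher and 3 lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.831, with 4 higher and 5 lower in the block fit). FSHR, the receptor of follicle-stimulating hormone, had 0.19 ± 0.23, PGR, the progesterone receptor, -0.64 ± 0.12, and INHBA, an activin subunit saturated in FID on 4 arrays and in control on 1, 0.45 ± 0.23. IGF2R had 1.25 ± 0.15 and INHBB, another activin subunit, 1.59 ± 0.20. Among the 18 markers of granulosa and cumulus cells, 0 passed over all genes, and 3 were higher and 6 lower when adjusted over the list alone (median -0.02, camera adjusted p = 0.774, with 3 higher and 6 lower in the block fit). KRT8, a keratin, had -2.36 ± 0.29 (adjusted p = 0.0545). In the list of ovulation and luteinisation, 1 of 19 passed, and 4 were higher and 6 lower when adjusted over the list alone (median -0.38, camera adjusted p = 0.774, with 5 higher and 5 lower in the block fit). This was SNAP25, a protein of vesicle fusion, which rose by 1.51 ± 0.14, and TIMP3, a metalloproteinase inhibitor above background in FID on 5 of 6 arrays, had -1.22 ± 0.18. LHCGR was not tested, since its 2 probes exceeded background on at most 3 of 6 arrays in FID and 1 of 6 in control.

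Of 22 EGF-like ligands and EGFR feedback genes, 0 passed over all genes, and 4 were higher and 3 lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.752, with 6 higher and 2 lower in the block fit). AREG, amphiregulin, had -0.60 ± 0.09 (adjusted p = 0.0679) with FID above background on 3 of 6 arrays, BTC, betacellulin, -0.01 ± 0.27 and ETV5, a transcription factor, 1.43 ± 0.18. EREG had no probe under its name. Of 16 genes of gap junctions and oocyte contacts, 0 passed over all genes and 1 was lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.335, with 0 higher and 4 lower in the block fit). GJA1, the gap junction protein connexin 43, had -1.04 ± 0.22 (adjusted p = 0.0973), and CLDN11, a claudin, had -1.27 ± 0.14 (adjusted p = 0.0505).

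Among 11 phosphodiesterases, 0 passed over all genes or when adjusted over the list alone (median 0.13, camera adjusted p = 0.320, with 1 higher and 0 lower in the block fit). PDE8A had 1.05 ± 0.27 (adjusted p = 0.127), PDE3B 0.37 ± 0.18, PDE4B 0.23 ± 0.47 and PDE3A 0.13 ± 0.09, and PDE4D was not tested, with its probe above background on 3 of 6 arrays in FID and 2 of 6 in control. Of 32 components of adenylyl cyclase, PKA, EPAC and CREB signalling, 0 passed over all genes, and 1 was higher and 3 lower when adjusted over the list alone (median -0.13, camera adjusted p = 0.701, with 2 higher and 6 lower in the block fit). PKIA, an inhibitor of PKA, had -1.44 ± 0.23 (adjusted p = 0.0698) and ATF1, a CREB family factor, -1.43 ± 0.20 (adjusted p = 0.0615) with 1 of its 3 probes of opposite sign. Of 13 genes of adenosine signalling and uptake, 0 passed over all genes and 1 was lower when adjusted over the list alone (median 0.03, camera adjusted p = 0.831, with 1 higher and 2 lower in the block fit), with -1.0 ± 0.15 for NT5E, which forms adenosine, and -1.38 ± 0.38 for ADK, which removes it.

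In the list of glycolysis and hypoxia, SLC2A3 rose and HK1, a hexokinase, fell by 0.87 ± 0.09, while 34 of 36 members did not pass, and 9 were higher and 5 lower when adjusted over the list alone (median 0.08, camera adjusted p = 0.335, with 9 higher and 5 lower in the block fit). In the oxidative stress list, GCLC, an enzyme of glutathione synthesis, rose by 1.95 ± 0.10 and TXNIP, an inhibitor of thioredoxin, fell by 3.05 ± 0.22. The other 29 of 31 did not pass, and 7 were higher and 3 lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.774, with 9 higher and 4 lower in the block fit). Of 31 genes of fatty acid metabolism and lipid storage, 0 passed over all genes, and 3 were higher and 4 lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.725, with 3 higher and 7 lower in the block fit). PNPLA2, a triglyceride lipase, had 1.40 ± 0.21 and HADHB, an enzyme of fatty acid oxidation, -0.88 ± 0.13. Of 30 genes of heat shock and the unfolded protein response, 0 passed over all genes, and 8 were higher and 1 lower when adjusted over the list alone (median 0.07, camera adjusted p = 0.221, with 9 higher and 1 lower in the block fit). DDIT4, a stress-induced inhibitor of mTOR, had 1.20 ± 0.16 and HSPB1, a small heat shock protein, 0.93 ± 0.12.

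In the list of inflammatory cytokines and NF-kappaB targets, STAT3, a transcription factor of cytokine signalling, rose by 1.20 ± 0.11, and 24 of 25 members did not pass. When adjusted over the list alone, 2 were higher and 2 lower (median -0.03, camera adjusted p = 0.831, with 4 higher and 2 lower in the block fit), and NFKB1 had 1.64 ± 0.24. In the list of TGF-beta, BMP and SMAD signalling, 1 of 23 passed, and 4 were higher and 5 lower when adjusted over the list alone (median -0.11, camera adjusted p = 0.725, with 3 higher and 5 lower in the block fit). This was TGFB2, a TGF-beta ligand, which was not above background in FID and was at least 3.37-fold lower there. BAMBI, a pseudoreceptor, had -1.02 ± 0.15 (adjusted p = 0.0620) on its brightest probe. Of its 3 tested probes 1 passed, and the lowest had -1.94. Of 23 WNT genes, 0 passed over all genes or when adjusted over the list alone (median 0.03, camera adjusted p = 0.831, with 1 higher and 2 lower in the block fit), with 0.61 ± 0.14 for AXIN1 and -0.87 ± 0.14 for WNT2B. Of 12 circadian clock genes, 0 passed over all genes and 2 were higher when adjusted over the list alone (median 0.10, camera adjusted p = 0.335, with 3 higher and 0 lower in the block fit), with 2.28 ± 0.24 for NFIL3 and 1.17 ± 0.19 for PER1, which was above background in control on 4 of 6 arrays. NFIL3 and PER1 are also members of the list of early genes that respond to cyclic AMP.

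Markers of theca cells (median 0.00 over 8 members, camera adjusted p = 0.774, with 1 higher and 0 lower in the block fit) and of endothelium (median 0.02 over 10 members, camera adjusted p = 0.725, with 0 higher and 0 lower in the block fit) had 0 members past the threshold over all genes and 0 when adjusted over the list alone. APOA1 had 0.43 ± 0.09, PTCH1, with 2 of its 3 tested probes of opposite sign, -0.18 ± 0.14, TEK 0.38 ± 0.11 and KDR -0.41 ± 0.14, with TEK above background on 5 of 6 arrays in each condition and KDR in FID on 3 of 6. In 8 of the lists that were not shifted, the median, the mean and the direction of camera did not all have the same sign: steroidogenesis, oxidative stress, inflammatory cytokines, hormone signals, gap junctions, WNT, adenosine, and ovulation and luteinisation.

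Each value printed for a gene is that of its brightest tested probe. For some of these genes another tested probe lay closer to 0 by more than 1 on the log2 scale, the closest with -0.38 for NPY1R, -1.91 for NDP, -1.59 for NMI, -1.48 for OAS1, -1.10 for TXNIP and -0.47 for UGDH. Likewise the closest had 0.54 for GADD45A, 0.10 for RRM2, 0.12 for ETV5, 0.06 for NR5A2 and 0.42 for STAR.

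Across tested probes, the ratios of the dye swap arrays of a replicate correlated at 0.553, 0.751 and 0.807 for replicates 1, 2 and 4, all positive after the sign was turned as the labels state the dyes. Averaged replicates correlated with each other at 0.562 to 0.591. Arrays of different replicates correlated at 0.562 to 0.613 in the same dye orientation and at 0.336 to 0.462 in opposite orientations. These correlations are across probes, which are not independent, and were not tested. A dye effect passed for 7369 probes in the fit of 6 arrays.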

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

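Values of single arrays were compared for 87 named genes without a saturated spot, 31 gene lists and 16 array measures. In 1 of these 134 items 1 array lay far from the other 5. Chance at 1 in 20 would give 6.7 if the arrays were independent. They are 3 dye swap pairs, so 6.7 does not apply, and a replicate that differs on both of its arrays is not readily found. For TLE1, the array of replicate 2 with FID in Cy5 had a log2 ratio of 3.97, against 2.20 to 2.83 on the others, all in the same direction. No explanation was tested for it.

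Positive control spots for E1A transcripts, which enter no comparison, gave signal on the arrays. Their median signals over 10 probe types ranged from 456 to 40880, above the negative control medians of at most 219. Their log2 ratio of FID over control, averaged over the arrays, lay between 0.07 and 0.32. It was taken from raw intensities without background correction or normalization, so it is not comparable with the other ratios printed here.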

How the results depend on the processing

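The alternative that keeps marked spots in the background fit was chosen after seeing the data; the others were planned. It gave 0 probes and 0 genes. The same count of 0 probes and 0 genes was obtained without background correction, with the background subtracted, with a trended and robust variance, with the authors' deposited ratios (identical tables, counted once), and without replicate 1, without replicate 2 or without replicate 4 (0 to 0). These 8 settings gave 4863 to 7428 probes at an unadjusted p under 0.05 in limma, with smallest adjusted p of 0.0505 to 0.249. With the deposited ratios all 557 probes had an adjusted p of at most 0.0867 and the same sign, and omitting a replicate leaves fewer samples. With marked spots kept except 1 of very high local background, 554 probes passed; otherwise the cause was not tested.

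Probes above background in both conditions on all 6 arrays gave 979 probes and 540 genes, with fewer probes tested. The random replicate block gave 5177 probes and 2567 genes, 6 arrays counted as independent 7189 and 3406, FID in Cy5 alone 1612 and 798, and FID in Cy3 alone 2268 and 1119. Without the replicate block, in an unpaired fit of 3 FID against 3 control channels, 1657 probes and 849 genes passed, 456 of the 557 among them. The mean of a gene's probes gave 504 genes. Arrays of 1 dye orientation keep the dye effect in their ratios, so their counts do not hold FID effects alone. Counting 6 arrays as independent takes the dye swap arrays of a replicate as separate replicates. How much these differences owe to that was not tested, nor was the cause of the others. Counts stayed within 1.5 times the main ones under 5 alternatives (557 to 763 probes), of which Aquantile normalization and the fold threshold of 1.5 removed or moved nothing and so test nothing.

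Lists numbered 4 to 7 under 19 of 21 alternatives, 5 to 7 where a replicate was omitted, and 0 with an estimated correlation. In that last setting no list had an unadjusted p under 0.05 in camera. Fry, which asks whether a list moves one way and not whether it differs from other genes, called 2. Prostaglandins had a fry adjusted p = 0.0259, with 9 members above 0 and 8 below. Glycolysis and hypoxia had a fry adjusted p = 0.0329, with 22 above and 14 below. Fry called none of the 5 lists that camera called (fry adjusted p = 0.126 to 0.372). The medians of the called lists kept their direction: 0.96 to 1.25 for early genes, -2.23 to -1.16 for interferon, -0.74 to -0.42 for actin, 0.28 to 0.93 for inhibitors and p53 targets, and 0.41 to 1.47 for oocyte markers. The 36 named genes past the threshold kept their direction in all 642 values, while 298 values of them were no longer past it. Each of the 36 had the same direction on every array, which was a rule for naming the largest rises and falls. Settings that use only some of the arrays could therefore not reverse them, and the other settings process the same arrays again. The 642 values thus say little about how stable these directions are. Among uncalled results, signs differed in 10 values of genes and 58 of lists. The mean dye swap correlation of 0.704 ranged from 0.607 to 0.760. Dim probes, and signal over background, limit which changes could be seen.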

Other observations

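All tests of explanations in this part were chosen after the results were seen, except the counts over choices of sign, which were planned. The genes in this paragraph were also chosen after their values were seen, among those past limma's threshold with the same direction on 6 of 6 arrays. NPY1R, a neuropeptide Y receptor, had -3.88 ± 0.23 (SE, n = 3) on its brightest probe, the only one of 3 to pass, and NPY5R, another, -2.39 ± 0.18. SYT4, a synaptotagmin, had 2.14 ± 0.12, SNAP25 1.51 ± 0.14 and CADPS, a priming factor of vesicles, 1.12 ± 0.09. HOMER1, a postsynaptic scaffold, had 2.43 ± 0.23, GRM8, a glutamate receptor, 1.86 ± 0.18, and GABRA4, a subunit of a GABA receptor with 1 probe of opposite sign, 1.61 ± 0.17. Other tested probes went down to 0.89 for SYT4 and 1.05 for HOMER1. No list of these genes was fixed or tested for enrichment.

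The genes here were chosen in the same way. SMPD3, which splits sphingomyelin, rose by 2.67 ± 0.10 and SGMS2, a sphingomyelin synthase, by 2.01 ± 0.20, while SGMS1, its relative, fell by 0.86 ± 0.09. DLL4, a Notch ligand, rose by 2.28 ± 0.19, while NRP1, a co-receptor of VEGF, fell by 2.52 ± 0.09 and NOS3, endothelial nitric oxide synthase, by 2.42 ± 0.22. NAMPT, which makes a precursor of NAD, rose by 1.90 ± 0.20 and SIRT1, a deacetylase that uses NAD, by 1.23 ± 0.11. Weaker probes of the same genes had -0.14 for NRP1, -0.04 for SGMS1 and 0.07 for SIRT1.

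Interferon-stimulated genes were lower in FID. A dye bias equal in both orientations cancels from the mean over them, so comparing its size with the shift cannot decide. The dye part, 0.5 times the difference between the list medians of the orientations, was 0.0229 ± 0.116 (SD, n = 3). The shift was -1.64 over both orientations. Array medians had a mean of -1.61 with FID in Cy5 and -1.66 with FID in Cy3. A dye bias alone would give opposite signs there, so these values argue against it. An interferon response in the control of 1 replicate is argued against by the weakest replicate median of -1.05. Fewer immune cells in the FID samples stay open, since only 3 of 15 blood and immune markers lay far enough above background in control to fall by the list's shift. These were PTPRC with 0.29, CD68 with 1.15 and HBA, a red cell gene, with 0.94 (median 0.94), too few to decide. A lower interferon response of the cumulus cells themselves under FID stays open as a hypothesis that was not itself tested.

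Oocyte markers were higher in FID, most of all in replicate 2. The dye part was 0.152 ± 0.365 (SD, n = 3) and the shift 1.09 over both orientations. An equal dye bias cancels from that shift, so its size decides nothing. Array medians had a mean of 1.24 (SD 1.37) with FID in Cy5 and 0.94 (SD 0.87) with FID in Cy3. Carried-over oocyte RNA in FID of replicate 2 stays open, since the list median without it was 0.41 with 0.72 and 0.10 in the other replicates, an SD of 0.44. So do probes near background, since the 7 members whose brightest tested probe was above background in both conditions on all 6 arrays had a median of 0.76 with an SD of 0.85. A difference in these transcripts between FID and control complexes was not tested apart from these.

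Actin, adhesion and YAP-SRF targets were lower in FID. The dye part was -0.0139 ± 0.105 (SD, n = 3) and the shift -0.48 over both orientations, from which an equal dye bias cancels whatever its size. Array medians had a mean of -0.50 with FID in Cy5 and -0.47 with FID in Cy3. A dye bias alone would give opposite signs there, so these values argue against it. Fewer stromal cells in the FID samples stay open. The 12 stroma and fibroblast markers outside the actin list had a median of -0.19, with -0.21, -0.48 and 0.05 in replicates 1, 2 and 4, and an SD of 0.75 over the markers.

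Turning the sign of 1 replicate at a time gives 4 choices of sign with the real one, too few for a share under 0.05, since the smallest share is 0.25. The real signs gave 557 probes and 292 genes, and the highest of the others 0 probes and 0 genes in limma, with 590 to 704 probes at an unadjusted p under 0.05 against 7561. As many calls were thus found in 1 of the 4 choices for probes and 1 for genes. With the random block the real signs gave 5177 probes and the highest other 0, so 1 of 4. For gene lists the real signs gave 5 and the highest other 6, so 2 of 4 choices gave as many.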
